A study of Mus musculus with 4 samples.

How the data were processed

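Single kidney cells of 2 control libraries and 2 libraries from mice with type 2 diabetic kidney disease, induced by a high-fat diet and streptozotocin, were captured in droplets and sequenced from the 5' end of transcripts, per the labels' protocols. Groups were taken from the titles, Control and Disease, and the disease from the series' design; the labels' disease state tag reads non-infection and infection for the same libraries. The deposited files hold, for each library, whole-number UMI counts per gene and cell, with gene symbols but no other gene identifiers. The reads were processed with Cell Ranger 7.1.0 against the build mm10, per the submitters' processing notes; the gene annotation and any later filter on cells are not given in the sources used here. Between 1.00% and 2.21% of the stored values of a library were 0, which sparse count matrices do not usually store, and for Cd74 they were 921 of 3597, 526 of 5695, 651 of 5276 and 1146 of 4533 stored values in control 1, control 2, diabetic 1 and diabetic 2. What step left them, and whether background RNA was subtracted upstream, is not given in the sources used here. How reads shared by near-identical genes were assigned is likewise not given in the sources used here.

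Cells with at least 500 UMIs, at least 300 genes and under 50% mitochondrial UMIs were kept, 29566 and 31292 in the controls and 23424 and 22134 in the diabetic libraries. Their median depths were 2033, 1205, 1817 and 1803.5 UMIs. Doublets were scored in each library with the Scrublet method of scanpy 1.11.5. The automatic threshold served in control 2 and diabetic 2. In control 1 and diabetic 1 it marked under 0.5% of the cells, so the top 5% of scores were left out instead. In control 1, control 2, diabetic 1 and diabetic 2, 1442, 3599, 1152 and 955 cells were left out.

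The remaining 99268 cells were clustered together. Counts were scaled to 10000 UMIs per cell and log-transformed, and 1735 variable genes, 40 principal components, 20 neighbours and the Leiden method (igraph 0.11.9) at resolution 1 gave 56 clusters. Clusters of at least 20 cells with at least 3 markers of a class among their 100 leading genes took that class's name, from markers fixed before the data were examined. The limits on markers of a second class, at 0.5 of the first class's score, or 0.3 for clusters deeper than 1.3 times their libraries, were set after the clusters were seen and before any gene was tested in a class. The clusters left unnamed held 1.78%, 2.47%, 2.94% and 3.12% of the cells of control 1, control 2, diabetic 1 and diabetic 2. The share of a class among kept cells was compared with an exact two-sided permutation test of the group means.

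Cells are not replicates, so counts were summed per library and class, and 1 profile per library entered each test. Genes were tested in the 6 main classes, fixed before the data were examined, and in intercalated, distal convoluted and connecting tubule, dendritic, T, B and NK cells, added later; each library held at least 10 cells of each. Genes of thin limb, mural and mesangial, plasma and fibroblast cells were not tested. The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with TMM normalization, the filterByExpr filter, Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. Levels are given as CPM, scaled to the UMIs of the class in a library. Gene lists fixed before the data were examined (pathways, complexes and cell type markers) were tested with camera (limma 3.58.1) at a preset correlation of 0.01 where at least 5 members were tested, with Benjamini-Hochberg adjustment over the lists of a class. The difference between the changes in podocytes and proximal tubule cells was tested as an interaction term in 1 model, with the library as a block. An exploratory pass of the main gene test over the classes came before the final code was written.

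Genes were named by a rule fixed before the data were examined. Among genes with an adjusted p under 0.05, both diabetic libraries on the same side of both controls and a mean of at least 20 CPM, the 10 largest rises and falls were named in proximal tubule cells and podocytes and the 5 largest in other classes. Predicted gene models were left out of the names. For a list, up to 4 members with the smallest p could be named, and 12 genes of interest were given where they passed the count filter. Results for some single genes that the rule names are not reported here. Which lists are discussed, the sex-linked one included, was chosen after the list results were seen. Gene positions are those of GENCODE vM21 on GRCm38 (mm10), 1-based.

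RNA of proximal tubule cells was estimated in each class as the summed CPM of the 32 proximal tubule markers, as a percent of their level in proximal tubule cells. Multiplied by a gene's proximal tubule level, this gives the share of its level that such RNA would account for, and values over 100% mean that the estimate exceeds the measured level. The share is set against the class's own level in each group, so a limit on it in both groups leaves out genes partly through their own change. Where a gene had 0 counts in a group, its fold was bounded with a floor of 3 counts over the group, which covers counting error only.

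The alternatives planned before the data were examined were RLE size factors, DESeq2 1.42.0, no gene filter, the replicate number as a block, leaving out each library, a stricter cell filter (1000 UMIs, 500 genes, 25% mitochondrial), doublets kept, each library clustered alone, and, for lists, an estimated correlation and fry. Without a library, the lone library of a group is assumed to vary like the other group. The estimated correlation and fry rest on the residual spread of 2 libraries per group, so a call by either was unlikely from the outset. The test was tested on simulated data with 200 changed genes. It recovered 12.9%, 35.7% and 92.6% of genes changed 1.5-fold, 2-fold and 4-fold in proximal tubule cells and 0%, 13.5% and 75.8% in podocytes. At 2-fold it recovered 40.3% in thick ascending limb, 29.4% in principal, 46.5% in endothelial and 41.7% in phagocyte cells. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9 were used.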

Results

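Kidney cells of mice were profiled by droplet-based single-cell RNA sequencing from the 5' end of transcripts. There were 2 control libraries and 2 libraries from mice given a high-fat diet and streptozotocin, a toxin of pancreatic beta cells, to induce type 2 diabetic kidney disease. The groups follow the titles (Control and Disease) and the series' design. The labels' disease state tag instead reads non-infection for the controls and infection for the libraries called diabetic here. The group differences below therefore do not tell diabetes from an infection, nor from direct effects of the diet or of streptozotocin. Control 1 and control 2 held 33891 and 46569 barcodes with 82079468 and 51703701 UMIs. Diabetic 1 and diabetic 2 held 25142 and 26087 barcodes with 55819217 and 56560696 UMIs. Control 2 was the shallowest, with a median of 861 UMIs per barcode against 1747, 1692.5 and 1543 in control 1, diabetic 1 and diabetic 2. After the cell filter the median mitochondrial share was 14.8% and 18.2% in the controls and 12.6% and 14.7% in the diabetic libraries. The libraries of a group differed beyond sampling noise, with a chi-square per degree of freedom of 193 for the controls and 56.6 for the diabetic pair. Nothing in the labels says that the libraries came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

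The question posed by the study's title concerned inflammation and the exchange between podocytes, the filtration cells of the glomerulus, and proximal tubule cells, which reabsorb most of the filtrate. Clusters were named by marker genes as 16 cell classes. Proximal tubule cells numbered 18301 and 16139 in the controls and 13871 and 11884 in the diabetic libraries, against 106, 52, 80 and 90 podocytes. Markers of proximal tubule cells were detected in every class. The proximal tubule markers reached 43.1% and 46.5% of their own-cell level in control podocytes, against 18.3% and 27.3% in diabetic podocytes.

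In diabetic proximal tubule cells the genes with the largest rise included complement component C3, with a log2 fold change of 4.63 ± 0.27 (SE, n = 2 libraries per group) and a mean of 1.90 CPM in controls against 49.8 CPM in diabetic libraries. The glutamine transporter gene Slc38a3 rose by 3.58 ± 0.24, and the cell cycle inhibitor gene Cdkn1a by 3.53 ± 0.24, from 9.91 to 120 CPM. The interferon-induced genes Bst2, Lgals3bp and Ifi27 rose by 3.52 ± 0.27, 3.51 ± 0.23 and 2.98 ± 0.29. Cyp4a14, a fatty acid omega-hydroxylase, rose by 3.43 ± 0.25, and Ucp2, a carrier of the inner mitochondrial membrane, by 3.07 ± 0.28. Wfdc2, which encodes a secreted protein with whey acidic protein domains, rose by 2.60 ± 0.23. Slc25a25, a mitochondrial nucleotide carrier gene, rose by 3.50 ± 0.42, with 64.6 CPM in diabetic 1 and 201 CPM in diabetic 2. C3 lies on chromosome 17 from 57203970 to 57228136, Cdkn1a on chromosome 17 from 29090976 to 29100727 and Slc38a3 on chromosome 9 from 107650634 to 107669530.

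Among the genes that fell in proximal tubule cells, Cyp4a12a, an androgen-dependent fatty acid hydroxylase on chromosome 4 from 115299046 to 115332815, had a log2 fold change of -2.55 ± 0.25, from 117 to 20.6 CPM. Azgp1, which encodes zinc-alpha-2-glycoprotein, changed by -2.31 ± 0.32, the cytochrome gene Cyp2d12 by -2.23 ± 0.31 and carboxypeptidase E, Cpe, by -2.12 ± 0.23. The tyrosine-degrading enzyme gene Hpd changed by -2.01 ± 0.32, the C-type lectin gene Clec2h by -1.94 ± 0.35, the phosphodiesterase gene Pde1a by -1.87 ± 0.20 and the ubiquitin ligase gene Rnf183 by -1.72 ± 0.22. The chaperone gene Hspa1a changed by -1.95 ± 0.36, and lipoprotein lipase, Lpl, by -1.82 ± 0.31. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 722 of 14258 genes passed, 447 higher and 275 lower, and the largest adjusted p among the 20 genes named here was 0.00437 (Hspa1a). Without control 1, control 2 or diabetic 2 the count was 1113, 1291 or 456, and the call for Lpl was lost without diabetic 1, at -1.43. With DESeq2 the calls for Clec2h and Hspa1a were lost.

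The mix of proximal tubule clusters differed between libraries. The most numerous was cluster 1 in control 1 and diabetic 2, with 4043 and 1970 cells, cluster 2 in control 2, with 4119, and cluster 3 in diabetic 1, with 2209. Some genes named above also lead single clusters: Azgp1 and Hpd lead cluster 1, Clec2h clusters 3 and 6, Cyp2d12 cluster 6, and Cyp4a12a cluster 10. C3, Slc25a25, Cyp4a14 and the gluconeogenic enzyme gene Pck1 lead cluster 24, which held 145 and 84 control cells and 222 and 465 diabetic cells. Cluster 5, whose 10 leading genes hold no marker of the class, was kept.

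**Figure D1:**
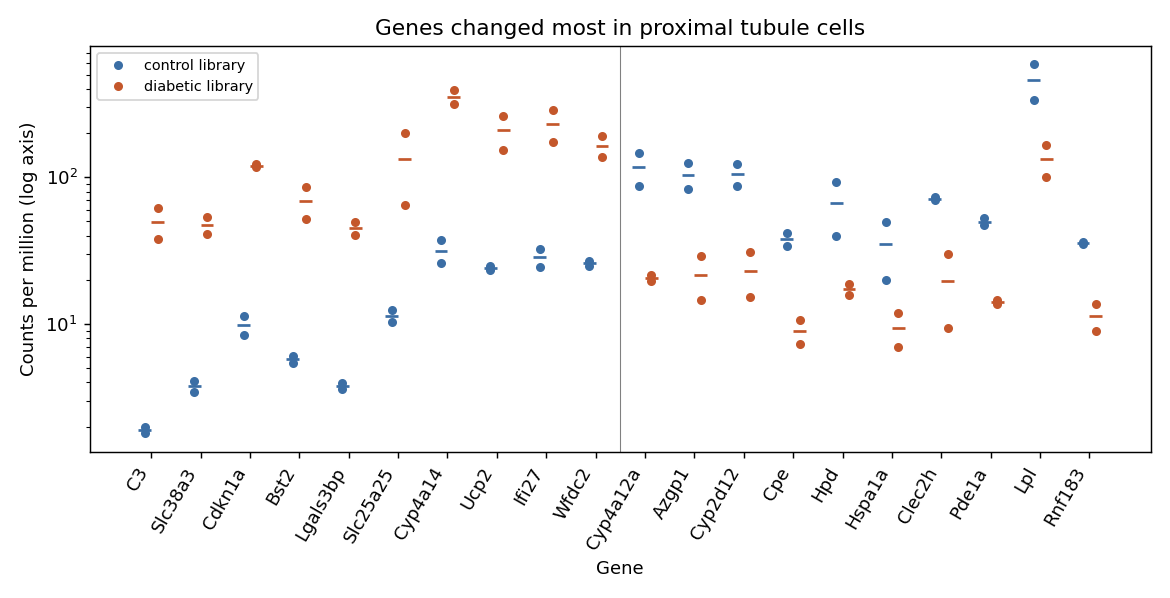
CPM (log axis) of the 10 genes with the largest rise and the 10 with the largest fall among those called in proximal tubule cells, 1 point per library and a line at each group's mean. C3 went from a mean of 1.90 to 49.8 CPM and Cyp4a12a from 117 to 20.6 CPM, with both diabetic libraries on the same side of both controls for each gene.

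Several genes had been chosen before the data were examined. The thioredoxin inhibitor gene Txnip, which responds to glucose, rose in proximal tubule cells by 2.08 ± 0.21. Spp1, which encodes osteopontin, rose by 1.57 ± 0.24, and the injury marker Havcr1 by 2.47 ± 0.46, at 0.293 CPM in controls and 1.75 CPM in diabetic libraries. Slc5a2, the glucose transporter targeted by gliflozins, was at 123 CPM in controls and 79.8 CPM in diabetic libraries, a log2 fold change of -0.67 ± 0.21 that was not called by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 0.0832) but was called with DESeq2 (-0.68), with the crossed replicate block (-0.67) and without control 2 (-0.76). The chemokine gene Ccl2 was at 1.88 ± 0.64 (adjusted p = 0.129 in the same edgeR test), and was called without control 2 (2.68), without diabetic 1 (2.52), with no gene filter (1.86) and with the replicate block (1.71). Cd44, Vegfa and Il1b were at 0.11 ± 0.24, -0.01 ± 0.21 and 0.08 ± 0.40, none of them called. Tnf and Fn1 did not pass the count filter in proximal tubule cells. The podocyte gene Nphs1 was at 0.276 CPM in control proximal tubule cells and at 0.445 CPM in diabetic ones, with no call.

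Interferon response genes rose together in proximal tubule cells: of 34 tested, 24 were higher, 0 lower and 10 not called, and 28 were higher when adjusted over the list alone. The antiviral genes Isg15 and Rtp4 rose by 3.83 ± 0.33 and 3.88 ± 0.37. The list was called with camera at its preset correlation (adjusted p = 4.2e-47), with adjusted p = 0.423 with an estimated correlation. Of 22 antigen presentation genes, 9 were higher and 13 not called (14 higher adjusted over the list alone), among them B2m at 1.29 ± 0.21 and the peptide transporter gene Tap1 at 1.85 ± 0.33. That list had adjusted p = 2.9e-11, and adjusted p = 0.423 with an estimated correlation. Of 21 markers of mononuclear phagocytes tested in proximal tubule cells, 2 were higher and 19 not called (8 higher and 1 lower adjusted over the list alone), with adjusted p = 3.5e-06 and adjusted p = 0.423 with an estimated correlation. Those 2 were Cd74, at 0.84 ± 0.21, and H2-Ab1, at 0.77 ± 0.19, and both calls were lost without diabetic 1 (0.95 and 0.81), without diabetic 2 (0.76 and 0.77) and with the replicate block (0.84 and 0.77). Another marker, C1qc, gained a call with no gene filter (0.90), with the replicate block (0.87) and with the crossed replicate block (0.92). It also gained one without control 1 (0.93), control 2 (0.94) or diabetic 1 (1.29). With doublets kept, Cd74 was at -0.12, H2-Ab1 was at 0.06 and the phagocyte marker list was no longer called (adjusted p = 0.676).

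Chemokine and cytokine genes were higher in 6 of 22 tested in proximal tubule cells, with 16 not called, and adjusted over the list alone 11 were higher and 1 lower. Cxcl1 rose by 1.77 ± 0.28 and Cxcl10 by 1.76 ± 0.30; the list had adjusted p = 3.1e-07, and adjusted p = 0.423 with an estimated correlation. Cxcl1 lost its call when each library was clustered alone, at 1.36. Of 27 genes of the NF-kB pathway and its targets, 4 were higher and 23 not called (9 higher adjusted over the list alone), with the adhesion molecule genes Vcam1 at 2.69 ± 0.39 and Icam1 at 1.01 ± 0.20. Bcl3 of this list, also called, lost its call with DESeq2 (0.80), with RLE size factors (0.80) and under several other settings. Relb lost its call with doublets kept (1.42) and without control 1 (1.19) or diabetic 2 (1.49). This list had adjusted p = 1.2e-05, and adjusted p = 0.423 with an estimated correlation.

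Tubular injury genes were higher in 10 of 28 tested, lower in 1 and not called in 17 (13 higher and 1 lower adjusted over the list alone), among them Cdkn1a, Spp1 and the stress cytokine gene Gdf15, at 2.05 ± 0.27. The list had adjusted p = 5.4e-15, and adjusted p = 0.423 with an estimated correlation. Of 29 genes of apoptosis, p53 and senescence, 7 were higher and 22 not called (13 higher adjusted over the list alone), with the p53 targets Phlda3 at 2.44 ± 0.27 and Zmat3 at 1.20 ± 0.20. It had adjusted p = 1.2e-08, and adjusted p = 0.423 with an estimated correlation. Genes of endoplasmic reticulum stress were higher in 10 of 28, with 18 not called (14 higher adjusted over the list alone), among them Manf at 1.58 ± 0.24, Atf3 at 1.34 ± 0.20 and Ddit3 at 1.08 ± 0.20. For these, adjusted p = 1.2e-13, and adjusted p = 0.441 with an estimated correlation. Of 31 immediate early genes, which also respond to tissue dissociation, 9 were higher in the same cells and 22 not called (17 higher adjusted over the list alone), with Btg2 at 2.40 ± 0.21 and Klf4 at 2.18 ± 0.23. That list had adjusted p = 1.2e-14, and adjusted p = 0.423 with an estimated correlation.

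Genes of fatty acid oxidation and ketogenesis were higher in 9 of 44 tested in proximal tubule cells, lower in 1 and not called in 34 (11 higher and 2 lower adjusted over the list alone). Besides Cyp4a14 and Ucp2, Pdk4, which restrains pyruvate oxidation, rose by 2.56 ± 0.22. The list had adjusted p = 2.5e-08, and adjusted p = 0.444 with an estimated correlation. Solute transport genes went both ways, with 3 of 39 higher, 5 lower and 31 not called (5 higher and 6 lower adjusted over the list alone), and the list was not called (adjusted p = 0.649). The phosphate transporter gene Slc34a3 changed by -1.41 ± 0.20, the sodium-glucose transporter gene Slc5a1 by 1.21 ± 0.19 and the organic anion transporter gene Slco4c1 by 1.18 ± 0.21. Of the 32 markers of the class itself, 3 were higher, 6 lower and 23 not called (4 higher and 11 lower adjusted over the list alone), and the list was not called (adjusted p = 0.232) except without control 2, when it was (adjusted p = 0.0219). Pck1 rose from 488 to 2635 CPM (2.39 ± 0.30), and Miox, which degrades inositol, changed by -1.23 ± 0.25, a call lost without diabetic 1 (-1.03) or diabetic 2 (-1.41).

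Of 10 sex-linked or sex-biased genes tested in proximal tubule cells, 1 was higher, 2 lower and 7 not called (1 higher and 3 lower adjusted over the list alone). The list was called lower (adjusted p = 0.0160), with adjusted p = 0.444 with an estimated correlation, and the call was lost without control 2 (adjusted p = 0.0674), diabetic 1 (adjusted p = 0.0692) or diabetic 2 (adjusted p = 0.0513). Cyp4a12a and the organic anion transporter gene Slco1a1, at -0.92 ± 0.22, were lower, Slc7a12 was higher at 1.37 ± 0.21, and Cyp7b1 was at -0.61 ± 0.22 with no call. The call for Slco1a1 was lost without diabetic 1 (-0.77) or diabetic 2 (-1.04), with the replicate block (-0.92) and with each library clustered alone (-0.95), and Cyp7b1 was called without control 2 (-0.80). The Y-linked gene Ddx3y was at 19.0, 31.3, 23.4 and 27.3 CPM in control 1, control 2, diabetic 1 and diabetic 2.

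For the exchange between podocytes and tubule cells, 43 ligand genes were tested in proximal tubule cells, of which 11 were higher, 2 lower and 30 not called (15 higher and 2 lower adjusted over the list alone). C3 and the growth factor gene Areg, at 4.33 ± 0.44 from 0.136 to 2.98 CPM, rose, while Angpt1 changed by -2.29 ± 0.25 and Mdk, which encodes midkine, by -1.65 ± 0.22. The ligand list had adjusted p = 7.3e-07, and adjusted p = 0.423 with an estimated correlation. Of 50 receptor genes, 4 were higher and 46 not called (5 higher adjusted over the list alone), namely Havcr1, Cd74, the ephrin receptor gene Epha2 at 1.57 ± 0.42 and Tnfrsf12a, the receptor of a cytokine of the tumour necrosis factor family, at 0.85 ± 0.21. The receptor list had adjusted p = 0.00165, and adjusted p = 0.50 with an estimated correlation. Its call was lost without control 1 (adjusted p = 0.159) and without diabetic 1 (adjusted p = 0.0574), and that of Tnfrsf12a without control 2 (0.66) and diabetic 2 (0.73), with doublets kept (0.86) and with each library clustered alone (0.81). Epha2, at 0.607 CPM in controls and 1.78 CPM in diabetic libraries, lost its call under 9 settings, among them DESeq2 (1.54) and the runs without control 1 (1.14), diabetic 1 (1.43) or diabetic 2 (1.70); of the 4, only Havcr1 lost its call under no setting. In all, 24 of 40 lists were called in proximal tubule cells, 22 higher and 2 lower. With an estimated correlation 0 were called. The count was also 0 with fry, which tests whether a list's genes move on balance in 1 direction without comparing it with other genes. Both have little power with 2 libraries per group, and with an estimated correlation 0 lists were called in any class tested. That outcome neither bears out the calls at the preset correlation nor argues against them.

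In diabetic podocytes 3 genes were called higher. The interferon-induced gene Ifi27l2a, on chromosome 12 from 103442167 to 103443680, rose by 4.27 ± 0.65 on the log2 scale (SE, n = 2 libraries per group), on 3 and 0 UMIs in controls against 42 and 23 in diabetic libraries. The MHC class II gene H2-Ab1 rose by 3.19 ± 0.69 on 9, 0, 68 and 17 UMIs, of which 1 cell held 44.1% in diabetic 1 and 82.4% in diabetic 2. Ucp2 rose by 1.86 ± 0.35, from 134 to 531 CPM. The 9 genes called lower, Apom (-2.98 ± 0.62), Cyp4b1 (-2.22 ± 0.38), Nat8f1 (-2.17 ± 0.36), Cyp2e1, Cndp2, Lrp2, Miox, Slc34a1 and Pdzk1ip1 (-1.57 ± 0.32), are genes that proximal tubule cells express. RNA of proximal tubule cells at the level of their 32 markers would give 65.4% to 126% of these genes' level in control podocytes and 77.2% to 168% in diabetic podocytes. Those markers include Cyp4b1, Cyp2e1, Lrp2, Miox and Slc34a1 themselves.

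The podocyte gene Nphs1, which encodes a slit diaphragm protein, was at -0.02 ± 0.33, and Vegfa, Spp1 and Txnip were at 0.35 ± 0.31, -0.06 ± 0.38 and 1.32 ± 0.34 (adjusted p = 0.115 for Txnip), with none called in podocytes; Txnip was called with each library clustered alone (1.92). edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 12 of 2988 genes. The counts without control 1, control 2, diabetic 1 and diabetic 2 were 42, 64, 7 and 38. Without diabetic 1, H2-Ab1 was at 1.86 and lost its call, as did 8 of the 9 lower genes, while Nat8f1 kept it. H2-Ab1 also lost its call with DESeq2 (3.61), under the stricter cell filter (3.10) and with doublets kept (1.16). Of the 9 lower genes, Cyp2e1 lost its call with DESeq2, 5 lost theirs under the stricter cell filter, 4 with doublets kept and 4, Nat8f1 among them, with each library clustered alone. Ucp2 alone was called among the 812 genes of which proximal tubule RNA would give at most 20% of the level in both groups. It lost its call under the stricter cell filter (1.77) and with doublets kept (1.67). The limit holds in each group, so a gene rare in controls, such as Ifi27l2a, can be left out through its low control level alone. That Ifi27l2a was left out does not show that proximal tubule RNA gave its rise. In simulated podocyte data the test recovered 13.5% of genes changed 2-fold and 75.8% of genes changed 4-fold.

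Of 23 proximal tubule markers tested in podocytes, 5 were lower and 18 not called (1 higher and 13 lower adjusted over the list alone), with adjusted p = 5.0e-23 and adjusted p = 0.337 with an estimated correlation. Solute transport genes were lower in 2 of 17, with 15 not called (10 lower adjusted over the list alone), and had adjusted p = 1.6e-15, and adjusted p = 0.297 with an estimated correlation. Of 5 interferon response genes tested, Ifi27l2a was higher and 4 were not called (5 higher adjusted over the list alone); Isg15 was at 3.48 ± 0.88, called only with no gene filter or with each library clustered alone (4.36). That list had adjusted p = 2.7e-09, and adjusted p = 0.297 with an estimated correlation. Of 12 antigen presentation genes, H2-Ab1 was higher and 11 were not called (8 higher adjusted over the list alone), with Cd74 at 2.46 ± 0.61 and H2-Eb1 at 3.39 ± 0.79, and the list had adjusted p = 4.0e-09, and adjusted p = 0.297 with an estimated correlation. Of 5 phagocyte markers, 1 was higher and 4 not called (4 higher adjusted over the list alone), at adjusted p = 1.9e-06, and adjusted p = 0.397 with an estimated correlation. Cd74 and H2-Eb1 were called without control 1 (3.10 and 3.19), without control 2 (2.21 and 3.43), without diabetic 2 (3.24 and 4.21), with no gene filter, with the replicate block and with each library clustered alone. The phagocyte marker call was lost without diabetic 1 (adjusted p = 0.102) and with doublets kept (adjusted p = 0.274).

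Of 36 slit diaphragm and foot process genes, 0 were called in podocytes, and 0 adjusted over the list alone, while the list as a whole was called higher (adjusted p = 0.00259), with adjusted p = 0.537 with an estimated correlation. The cell cycle inhibitor gene Cdkn1c was at 0.76 ± 0.35 and the collagen gene Col4a3 at 0.73 ± 0.34. The list's call was lost without control 2 (adjusted p = 0.149) and without diabetic 1 (adjusted p = 0.229). Of 17 genes of endoplasmic reticulum stress, 0 were called (2 higher adjusted over the list alone), with Manf at 1.58 ± 0.43 (called without control 2, at 1.66), and the list had adjusted p = 1.2e-04, and adjusted p = 0.297 with an estimated correlation. In all, 18 of 26 lists were called in podocytes, 11 higher and 7 lower. The count was 0 with an estimated correlation or with fry, which have little power with 2 libraries per group. Proximal tubule markers stood at 43.1% and 46.5% of their own-cell level in control podocytes and at 18.3% and 27.3% in diabetic ones. Levels are relative to all RNA of the droplets, so less of that RNA raises the podocytes' own genes. How much of the rise of the higher lists this gives was not tested.

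The change between groups was compared between podocytes and proximal tubule cells in 1 model, and 46 of 13351 genes differed, 15 more positive in podocytes and 31 more negative. The genes with an unadjusted p under 0.05, counted below, were no more than chance alone would give among 13351 tested. Spp1, which rose in proximal tubule cells, differed by -1.58 ± 0.30 (adjusted p = 2.5e-04 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The genes with the smallest p, named after their values were seen, were Ephx1, which encodes a microsomal epoxide hydrolase, at -4.41 ± 0.54, Btg2 at -2.21 ± 0.29, the calcium-binding protein gene S100g at -1.83 ± 0.30, the netrin receptor gene Unc5c at 1.77 ± 0.29 and Wfdc2 at -2.46 ± 0.41. The more negative genes included Slc34a1, Lrp2 and Nat8f1, among those for which proximal tubule RNA would give most of the podocyte level. The count was 0 without control 1 (with 632 genes at an unadjusted p under 0.05 in all libraries), 5 without control 2, 7 without diabetic 1 and 23 without diabetic 2.

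In cells of the thick ascending limb, which reabsorbs salt in the loop of Henle, Cdkn1a rose by 4.63 ± 0.30 on the log2 scale (SE, n = 2 libraries per group), from 9.54 to 244 CPM. Lcn2, a marker of tubular injury, rose by 4.46 ± 0.31, the leukotriene synthase gene Ltc4s by 3.90 ± 0.32, Cxcl10 by 3.58 ± 0.31 and Gdf15 by 2.88 ± 0.30. The desaturase gene Scd2 changed by -1.99 ± 0.30 and Lpl by -1.88 ± 0.26. Hsd3b2, Tmem252 and Slco1a1 were called lower (-2.35 ± 0.29, -2.22 ± 0.35 and -1.89 ± 0.28), and proximal tubule RNA would give 110% to 121% of their level in controls. Of 25 tubular injury genes, 12 were higher and 13 not called (16 higher adjusted over the list alone), with adjusted p = 4.1e-33, and adjusted p = 0.165 with an estimated correlation. Of 28 interferon response genes, 13 were higher and 15 not called (20 higher adjusted over the list alone), with Isg15 at 2.40 ± 0.28, adjusted p = 2.7e-25, and adjusted p = 0.169 with an estimated correlation. Proximal tubule markers were lower in 15 of 32, higher in 2 and not called in 15 (2 higher and 20 lower adjusted over the list alone), with adjusted p = 3.3e-18, and adjusted p = 0.281 with an estimated correlation. They stood at 27.6% and 24.4% of their own-cell level in control thick ascending limb cells against 16.7% and 18.3% in diabetic ones.

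edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 459 of 10895 genes in thick ascending limb cells, 223 higher and 236 lower. DESeq2 called 204, and 251 were called among genes with a proximal tubule RNA share of at most 20%, 177 higher and 74 lower. Without control 2, diabetic 1 and diabetic 2 the count was 993, 173 and 199.

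In collecting duct principal cells, which regulate water reabsorption, Cdkn1a rose by 3.50 ± 0.40 and its fellow p53 target Phlda3 by 3.44 ± 0.52 (log2, SE, n = 2 libraries per group). The proton pump gene Atp12a rose by 4.97 ± 0.74 on 3 and 1 UMIs in controls against 9 and 51 in diabetic libraries, and Grem1, an antagonist of bone morphogenetic proteins, by 4.48 ± 0.75 on 6, 0, 51 and 10 UMIs. The call for Grem1 was lost without diabetic 1, at 2.87. Cyp4a14 was called higher at 3.39 ± 0.51, with 118% to 151% of its level accounted for by proximal tubule RNA. Ptger1, a prostaglandin receptor gene, changed by -1.63 ± 0.26, and the mucin-like gene Fcgbp by -2.64 ± 0.55, a call lost without control 1 (-2.60), control 2 (-2.68) or diabetic 2 (-1.95). Cyp4b1, Miox and Igfbp4, called lower, had proximal tubule shares of 99.5% to 120% in controls. Miox lost its call without diabetic 2 (-1.27) and Igfbp4 without diabetic 1 (-1.27) or diabetic 2 (-1.62). With the replicate block the calls for Ptger1, Miox, Igfbp4 and Fcgbp were lost, and with each library clustered alone that for Cyp4b1 (-1.07). Of 27 interferon response genes, 10 were higher and 17 not called (19 higher adjusted over the list alone), with Bst2 at 1.94 ± 0.25, adjusted p = 1.4e-42, and adjusted p = 0.437 with an estimated correlation. Proximal tubule markers in these cells were at 14.1% and 19.0% of their own-cell level in controls and 16.6% and 10.4% in diabetic libraries. edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 48 of 7870 genes in principal cells, 39 higher and 9 lower (29 and 3 among genes with a proximal tubule RNA share of at most 20%), with 95 without control 1 and 120 without control 2. DESeq2 called 23, without Cdkn1a, Grem1, Fcgbp and Igfbp4, and 716 were called when each library was clustered alone.

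In endothelial cells Cyp26b1, which degrades retinoic acid, rose by 3.72 ± 0.23 on the log2 scale (SE, n = 2 libraries per group), from 21.5 to 308 CPM. The interferon-induced genes Oas2, Ifi206 and Ifi27l2a rose by 3.18 ± 0.36, 2.90 ± 0.29 and 2.70 ± 0.29, and the urea transporter gene Slc14a1 changed by -1.91 ± 0.24. Cyp26b1 and Slc14a1 also lead endothelial clusters 18 and 20. Cyp4a14 was called higher, and Mdk, Hsd3b2, Apom and Serpinf2 lower, and proximal tubule RNA would give 83.2% to 118% of the level of these 5 genes in control endothelial cells. Of 35 interferon response genes, 26 were higher and 9 not called (32 higher adjusted over the list alone), with adjusted p = 5.6e-62, and adjusted p = 0.421 with an estimated correlation. Of 21 antigen presentation genes, 8 were higher and 13 not called (12 higher adjusted over the list alone), with H2-Q7 at 1.15 ± 0.21, adjusted p = 1.3e-08, and adjusted p = 0.421 with an estimated correlation. Proximal tubule markers were lower in 9 of 32, higher in 2 and not called in 21 (2 higher and 17 lower adjusted over the list alone; adjusted p = 1.0e-10, and adjusted p = 0.421 with an estimated correlation), at 34.3% and 39.4% of their own-cell level in controls and 31.2% and 24.4% in diabetic libraries. In endothelial cells edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 262 of 11182 genes, 149 higher and 113 lower. Among genes with a proximal tubule RNA share of at most 20% it was 175 higher and 20 lower. That limit leaves out genes partly through their own change. The median log2 fold change of the genes kept was 0.152, against -0.00835 over all tested, so the skew is partly set by the limit. Under the stricter cell filter 27 were called, without Cyp4a14, Hsd3b2 and Serpinf2, and without control 1, control 2 and diabetic 2 the count was 576, 433 and 117.

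In mononuclear phagocytes the chemokine gene Ccl7 rose by 4.57 ± 0.29 on the log2 scale (SE, n = 2 libraries per group), from 7.07 to 171 CPM. The MHC class I gene H2-M2 rose by 3.89 ± 0.35, the sialic acid receptor gene Siglec1 by 3.14 ± 0.31, the interferon regulatory factor gene Irf7 by 2.85 ± 0.31 and the coagulation factor gene F13a1 by 2.74 ± 0.35. The chaperone genes Dnajb1 and Hspa1b changed by -2.53 ± 0.47 and -2.04 ± 0.24, and Dnajb1 was at 824 and 194 CPM in the controls against 94.7 and 83.8 CPM in the diabetic libraries. Haemoglobin genes had 0 counts in diabetic phagocytes, so that Hbb-bs was at least 184-fold, Hba-a1 at least 126-fold and Hba-a2 at least 86.6-fold lower against a floor of 3 counts over the group's 5856173 UMIs. The 237 and 75 control UMIs of Hbb-bs came from 3 and 2 cells.

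Of 35 interferon response genes, 21 were higher in phagocytes and 14 not called (24 higher and 1 lower adjusted over the list alone), with adjusted p = 7.3e-33, and adjusted p = 0.384 with an estimated correlation. Heat shock genes were lower in 5 of 16 and not called in 11 (7 lower adjusted over the list alone), with Hspa1a at -1.79 ± 0.27, adjusted p = 4.8e-06, and adjusted p = 0.415 with an estimated correlation. Proximal tubule markers were lower in 11 of 31, higher in 2 and not called in 18 (2 higher and 20 lower adjusted over the list alone; adjusted p = 8.8e-14, and adjusted p = 0.384 with an estimated correlation), at 18.0% and 23.1% of their own-cell level in controls and 15.5% and 11.6% in diabetic phagocytes. edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 301 of 10116 genes in phagocytes, 184 higher and 117 lower (185 and 35 among genes with a proximal tubule RNA share of at most 20%), with 749 without control 1 and 593 without control 2. DESeq2 called 195, without the call for Dnajb1, which was also lost with the crossed replicate block (-2.22). Hspa1a and Hspa1b, like Hba-a1 and Hba-a2, are near-identical copies, so their separate values are uncertain.

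**Figure D2:**
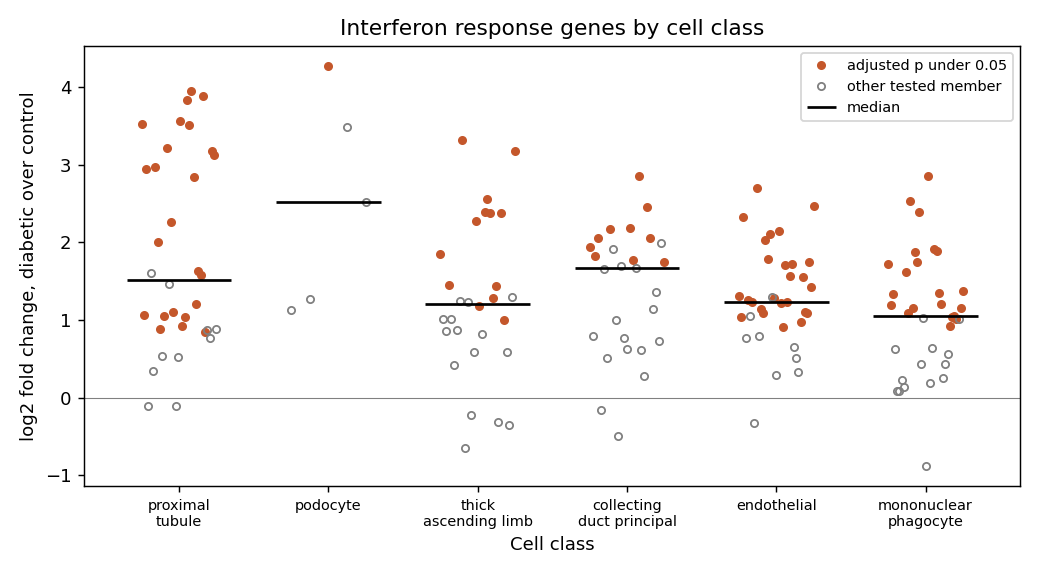
Log2 fold change (diabetic over control) of each tested interferon response gene in the 6 main cell classes, with filled points for genes with an adjusted p under 0.05, open points for the others and a line at the median. Filled points number 24 in proximal tubule, 1 in podocyte, 13 in thick ascending limb, 10 in principal, 26 in endothelial and 21 in phagocyte cells, and each filled point lies above 0.

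The share of T cells among kept cells was 1.59% ± 0.69 in controls and 3.55% ± 0.18 in diabetic libraries (SD, n = 2 each). NK cells made up 0.220% ± 0.076 and 0.579% ± 0.18, and dendritic cells 0.871% ± 0.41 and 1.68% ± 0.041. Lower shares were found for thin limb cells, at 1.48% ± 0.86 against 0.462% ± 0.019, and principal cells, at 1.26% ± 0.34 against 0.563% ± 0.029. Endothelial cells made up 6.93% ± 2.1 against 4.46% ± 1.3, and mural and mesangial cells 0.795% ± 0.012 against 0.619% ± 0.0058. In these 7 of 16 classes the groups did not overlap, which chance gives for 33.3% of classes, and each had an exact two-sided permutation p of 0.333, the smallest that 2 against 2 libraries can give. The groups overlapped for proximal tubule cells (61.7% ± 4.8 and 59.2% ± 4.4), podocytes (0.282% ± 0.13 and 0.392% ± 0.046) and phagocytes (4.34% ± 1.8 and 6.13% ± 1.5), and the proximal tubule difference of -2.48 percentage points turned to 0.918 without control 1 and 0.605 without diabetic 2. The cell filter kept 87.2%, 67.2%, 93.2% and 84.8% of the barcodes of control 1, control 2, diabetic 1 and diabetic 2, and control 2 was the shallowest, either of which can set shares. Doublet removal also differed, taking 4.88%, 11.5%, 4.92% and 4.31% of their cells. The principal cell share also leaves out cluster 22 (968 cells, led by Aqp6, Hsd11b2, Scnn1g and Rhbg). It was left unnamed for markers of 2 classes, under a limit set after the clusters were seen. This cluster made up 0.825%, 1.04%, 0.920% and 1.15% of the cells of control 1, control 2, diabetic 1 and diabetic 2. Under the stricter cell filter endothelial cells overlapped between the groups (4.78% and 4.67%), while proximal tubule cells (66.6% and 58.9%), phagocytes (3.54% and 7.93%) and B cells (0.481% and 0.829%) did not. When each library was clustered alone the principal cell difference turned from -0.693 to 0.937 percentage points, that of podocytes turned from 0.110 to -0.157 (0.758% and 0.602%, with overlap), thin limb cells (1.65% and 1.49%) and dendritic cells (0.827% and 1.18%) overlapped, and phagocytes (4.74% and 7.54%) did not. No cluster was then named as NK cells in control 2, as mural and mesangial cells in diabetic 2, or as fibroblasts in control 1 or diabetic 2. The T cell share did not overlap under any of these settings or with doublets kept.

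**Figure D3:**
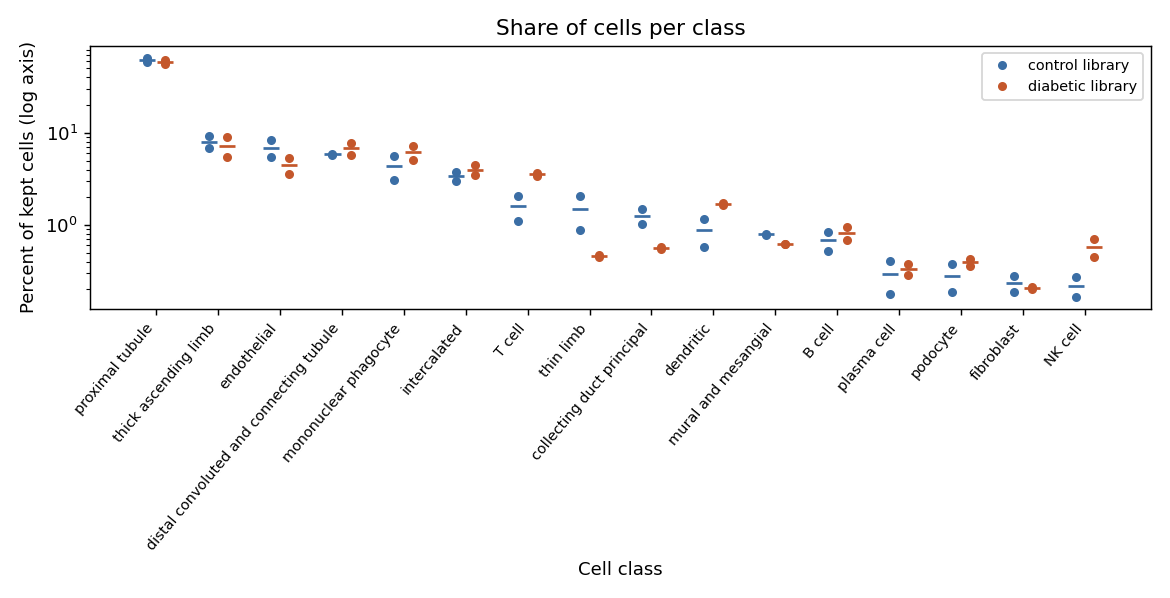
Percent of kept cells (log axis) in each of the 16 named cell classes, 1 point per library and a line at each group's mean. T cells lay at 1.10% and 2.08% in the controls and at 3.67% and 3.42% in the diabetic libraries, and proximal tubule cells were the most frequent class in each library.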

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

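The tests of podocyte free RNA, the run without cluster 5 and the tests on stored zeros were chosen after the data they bear on were seen; the other tests were set out before their own values were computed, but after the exploratory pass of the gene test.

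A closer look is warranted at the 46 genes whose change differed between podocytes and proximal tubule cells, 31 of them more negative in podocytes, and at the 9 genes called lower in diabetic podocytes. For the 46 genes as a set no explanation was tested. Against the fall of the 9 genes being a change within podocytes alone stands the level of proximal tubule markers, which without the called genes was at 44.2% and 46.7% of the own-cell level in control podocytes and at 18.7% and 28.3% in diabetic ones. The level of those 27 other markers, times each gene's own level in proximal tubule cells, gave a predicted fold for each of the 9 genes. The prediction thus holds both the lower share of such RNA and any change of the gene in proximal tubule cells. It ran from a log2 fold change of -1.14 for Lrp2 to -2.16 for Apom. The median of observed minus predicted log2 fold change was -0.36 (median absolute deviation 0.32). The difference was below 0 for 8 of the 9, down to -0.80 for Nat8f1, and was 0.29 for Miox. Proximal tubule RNA in the podocyte droplets is therefore a candidate explanation for most of the fall, through its lower share and the genes' own change in proximal tubule cells together. It leaves a part of the fall over in most of these genes. The part due to the lower share alone was not separated. What remains open, and untested, is a loss of these transcripts from podocytes themselves in diabetes.

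Of 34 interferon response genes 24 were called higher in proximal tubule cells (list adjusted p = 0.423 with camera at an estimated correlation). There 2 of 21 markers of mononuclear phagocytes were also called higher, calls that were lost without diabetic 1, without diabetic 2 or with doublets kept. A further marker, C1qc, gained a call under other settings. If more phagocyte RNA in the diabetic droplets were the cause, at unchanged levels in phagocytes, both would rise by a like percent of their phagocyte level. The 24 interferon genes, taken because they were called higher in these cells, rose by a median of 5.38%. The 8 phagocyte markers, chosen for this test, rose by 0.0623%, a ratio of 86.3. Interferon genes also rose in phagocytes themselves. A steady amount of phagocyte RNA could therefore raise these genes and not the markers, which the ratio does not test. In proximal tubule cells a median of 35.6% of the stored values of these markers were 0 (40.5% for Cd74), against 4.67% for the interferon genes. With each stored 0 counted as 1 UMI the ratio was 62.3. This still argues against an increase of such RNA as the main source, unless larger amounts of phagocyte markers were subtracted upstream. The sources used here do not settle that, and a steady amount of such RNA was not tested. The labels name 0 batches that cross the groups, so a difference between library batches and the effect of diabetes cannot be told apart. The labels' disease state tag reads infection for the diabetic libraries and non-infection for the controls, against their titles and the series' design, and no test here separates an infection from diabetes. A response of the cells to diabetes, to the diet or streptozotocin directly, or to an infection stays open as a hypothesis.

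The 722 genes changed in proximal tubule cells could come from a different mix of proximal tubule clusters. With each library given the same mix, the median size of their log2 fold change was 0.93 in place of 1.01. The ratio was 0.925 (0.915 to 0.935 leaving out each library), and 719 genes kept their sign. This argues against the mix of clusters as the main cause for the genes as a set. It does not cover shifts within a cluster, nor single genes, such as those that lead 1 cluster. Without cluster 5, whose 10 leading genes hold no marker of the class, 698 genes were called, 688 of them shared, which argues against low-quality cells of that cluster. A difference between batches, which the labels do not allow to be tested, the diabetes itself and the infection that the disease state tag names stay open. Direct effects of the high-fat diet and of streptozotocin go with the diabetic group and stay open too.

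Among cells left without a class name, cluster 28 (713 cells, led by Msmp, Ptgds, Stc2, Cp and Ankrd1) made up 0.306% and 0.354% of the controls and 1.13% and 1.31% of the diabetic libraries, a ratio of 3.70. Cluster 39 (62 cells, led by markers of phagocytes and T cells such as Ms4a7, C1qa, Cd3e and Cd3d) made up 0.0249% and 0.0650% against 0.0943% and 0.0755%, a ratio of 1.89.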

How the results depend on the processing

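Among the settings below, the crossed pairing, the run without cluster 5 and the limit on proximal tubule RNA were chosen after the data were seen. The cause of each difference was not tested unless stated. The limit on proximal tubule RNA leaves out genes partly through their own change. For lists, an estimated correlation and fry have little power with 2 libraries per group, so their counts of 0 decide nothing. In proximal tubule cells (722 genes) the count was 1087 with no gene filter, 424 with each library clustered alone and 456 to 1291 leaving out each library. In podocytes (12 genes) it was 21 with RLE size factors, 34 with no gene filter, 5 under the stricter cell filter, 6 with doublets kept, 46 with each library clustered alone, 1 among genes with a proximal tubule RNA share of at most 20% (812 genes tested in place of 2988) and 7 to 64 leaving out each library. In thick ascending limb cells (459) it was 204 with DESeq2, 251 under that limit on proximal tubule RNA (3666 genes tested in place of 10895) and 173 to 993 leaving out each library. In principal cells (48) it was 23 with DESeq2, 126 with no gene filter, 76 with doublets kept, 716 with each library clustered alone and 68 to 120 leaving out each library. In endothelial cells (262) it was 144 with DESeq2, 463 with no gene filter, 27 under the stricter cell filter, 413 with doublets kept and 117 to 576 leaving out each library. In phagocytes (301) it was 195 with DESeq2, 640 with no gene filter, 460 with doublets kept, 672 with each library clustered alone and 202 to 749 leaving out each library. The 24 lists called in proximal tubule cells and the 18 in podocytes became 0 and 0 with an estimated correlation and 0 and 0 with fry, and 19 to 27 and 10 to 19 leaving out each library. The 46 genes that differed between podocytes and proximal tubule cells became 21 under the stricter cell filter, 5 with the library block left out and 0 to 23 leaving out each library.

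Deviations of same-numbered libraries from their group means gave no sign that the replicate numbers pair the libraries. They correlated at -0.142 in proximal tubule, -0.0564 in podocyte, -0.295 in thick ascending limb, -0.0967 in principal, -0.204 in endothelial and -0.178 in phagocyte cells. With 2 libraries per group the crossed pairing gives the same values with the sign turned, so these values establish neither pairing. With the replicate block the counts were 778, 36, 339, 20, 267 and 403 in that order. With the crossed pairing as a block the counts were 1195 in proximal tubule, 985 in thick ascending limb, 638 in endothelial and 290 in phagocyte cells. That pairing was picked from these same data, so calls made with it lend no support to a gene.

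The principal cell share difference turned to 0.937 percentage points with each library clustered alone, the endothelial difference went from -2.47 to -0.109 percentage points under the stricter cell filter and that of proximal tubule cells from -2.48 to -7.69, and the thin limb difference from -1.02 to -0.156 with each library clustered alone. Cd74 in proximal tubule cells turned to a log2 fold change of -0.12 with doublets kept. Over all named genes and settings, 1678 values kept their side of the threshold, 98 lost their call, 50 gained one and 1 reversed. Reversed means here a change of sign with a call in either run, so sign changes of genes called in neither are among the 1678. Genes that a setting did not test, or gave no adjusted p, were not counted, such as those left out by the limit on proximal tubule RNA. Over the lists 241 kept their side, 50 lost their call and 1 gained it. Over the shares 102 moved by less than the spread between replicates, 9 by more and 1 reversed. For shares, reversed means a change of sign in a class whose groups did not overlap in the main setting. The podocyte difference, whose groups overlapped, also changed sign with each library clustered alone (from 0.110 to -0.157), and that of fibroblasts under the stricter cell filter (from -0.028 to 0.025). Leaving out 1 library also changed the sign of the difference in proximal tubule cells (0.918 without control 1, 0.605 without diabetic 2), thick ascending limb cells (0.371 without control 1, 1.02 without diabetic 1), distal convoluted and connecting tubule cells (-0.052 without diabetic 2), B cells (-0.027 without control 1), plasma cells (-0.072 without control 1, -0.0031 without diabetic 1) and fibroblasts (0.019 without control 2), whose groups all overlapped.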

Other observations

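The values in this part come from comparisons outside the 6 main classes, apart from the lipid list in proximal tubule cells, and were chosen after the results were seen, although the genes follow the fixed rule. For the classes outside the main 6, no alternative cell filter, clustering or removal of a library was run for the gene tests.

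In intercalated cells, which secrete acid or base, Cdkn1a rose by 2.30 ± 0.23 on the log2 scale (SE, n = 2 libraries per group). The kallikrein gene Klk1 changed by -1.76 ± 0.26, from 9620 to 2852 CPM, the sterol synthesis gene Msmo1 by -1.64 ± 0.24 and Lpl by -2.13 ± 0.33. Of 29 genes of lipid synthesis and storage, 7 were lower and 22 not called (1 higher and 11 lower adjusted over the list alone), with the squalene epoxidase gene Sqle at -1.90 ± 0.31. That list had adjusted p = 5.3e-11, and adjusted p = 0.322 with an estimated correlation. In cells of the distal convoluted and connecting tubule, 5 of 30 genes of the same list were lower and 25 not called (1 higher and 11 lower adjusted over the list alone), with Scd2 at -1.39 ± 0.28, adjusted p = 9.2e-06, and adjusted p = 0.354 with an estimated correlation. Cxcl10 rose there by 4.28 ± 0.40, Phlda3 by 3.67 ± 0.40 and the testis-type cytochrome oxidase subunit gene Cox6b2 by 3.12 ± 0.29. In proximal tubule cells the lipid list was not called (adjusted p = 0.646), although 6 of its 33 genes were lower, 1 was higher and 26 were not called (7 higher and 8 lower adjusted over the list alone). Among them the cholesterol transporter gene Abca1 was at -2.03 ± 0.34, and the list's median was 0.18 against a mean of -0.02. edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 140 of 10750 genes in intercalated cells (64 higher, 76 lower) and 123 of 11177 in distal convoluted and connecting tubule cells (83 higher, 40 lower).

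Interferon response genes were higher in 11 of 31 tested in dendritic cells, 8 of 24 in intercalated cells and 10 of 30 in distal convoluted and connecting tubule cells, with 20, 16 and 20 not called (23, 15 and 20 higher adjusted over the list alone). Their adjusted p was 3.4e-24, 1.7e-25 and 3.0e-39, and adjusted p = 0.505, 0.336 and 0.148 with an estimated correlation. Proximal tubule markers were lower in 13 of 29, higher in 2 and not called in 14 in dendritic cells (2 higher and 19 lower adjusted over the list alone; adjusted p = 3.7e-22, and adjusted p = 0.505 with an estimated correlation), where they were at 23.5% and 17.9% of their own-cell level in controls and 14.5% and 8.66% in diabetic libraries. In B cells 5 of 3681 genes were called, with the proximal tubule markers Cyp4a14 at 4.38 ± 0.61 and Pck1 at 2.65 ± 0.33, the chemokine gene Ccl5 at 3.10 ± 0.52 and the neutrophil genes S100a9 and S100a8 at least 58.9-fold and 19.0-fold lower, against a floor of 3 counts over the diabetic group's 554832 UMIs. Proximal tubule markers were at 32.4% and 47.2% of their own-cell level in control B cells and 37.6% and 29.3% in diabetic ones.

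In T cells 0 of 8060 genes were called by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with 506 at an unadjusted p under 0.05, and no other tool was run. The smallest p was that of Ly6c1, at -1.88 ± 0.21 (adjusted p = 0.0516), and Tox, which marks chronically stimulated T cells, was at 1.61 ± 0.23 with no call. In NK cells 0 of 2357 genes were called, with 169 at an unadjusted p under 0.05 by the same test alone, and granzyme B, Gzmb, was at 1.83 ± 0.37 (adjusted p = 0.144).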
